A study of Homo sapiens with 6 samples.

How the data were processed

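Gene expression was measured on 6 Affymetrix arrays in 3 human ovarian cancer cell lines, ES-2, OVCAR-3 and SKOV-3. Each line had been transfected once with miR-blank, the control, and once with miR-135a-3p, a mature arm of the miR-135a hairpin. Total RNA was extracted with a column kit, and labelled cDNA was made with a whole-transcript kit and biotin, per the labels' protocols. Whether the transfected material was a synthetic RNA or a vector, the dose and the time of harvest were not given in the sources used here.

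The deposited values were log2 signals of 53617 probe sets, 1 column per array. RMA, Affymetrix Expression Console 1.4 and Transcriptome Analysis Console 3.0 are named, per the submitters' processing notes, with no role or order. RMA corrects background, makes the distributions of the arrays equal and summarises the probes of a set, so a shift of most genes in one direction would be removed. Array medians lay between 4.16 and 4.23, the quartiles between 2.79 and 2.88 and between 5.85 and 5.90, and the highest signals near 13.6. The scale was read as log2 from these values and from the named method, and the values were not centred per gene. The table held no detection calls, so a low signal could not be told from background, and the number of arrays limits the precision.

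Probe sets were named through the platform annotation and a RefSeq gene table of assembly GRCh38.p14, matched by Entrez identifier, which was used for names and neighbours only. Of the probe sets, 16098 had 1 gene symbol, 0 had several and 37519 were unnamed here. The 16098 probe sets stood for 14884 symbols, of which 779 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays was kept. Genes with a mean log2 value of at least 5 were tested, which left 8620 genes, 7936 of them protein-coding. A further 10271 unnamed probe sets passed the same filter and entered a separate count. AGO2 and DICER1 were not analysed here.

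The transfections were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with the cell line as a block. The arrays of a line are a pair because they come from the same cell line. Deviations from the group means correlated at 0.90, 0.91 and 0.76 within ES-2, OVCAR-3 and SKOV-3 and below 0 between all arrays of different lines. Deviations from a mean of 3 arrays sum to 0, which pushes the values between lines below 0, so their sign shows nothing. The signals themselves correlated at 0.987, 0.984 and 0.979 within these lines and at 0.942 to 0.953 between lines. No pair of arrays held identical columns. The replicates of the comparison are the 3 lines, with 1 array per line and transfection, so the spread combines differences between lines with technical scatter. Within a line, sizes, counts of genes past 2-fold and percentiles of list medians were given as descriptions, with no test. The lines were compared with limma with the transfection as a block, at an adjusted p under 0.05 and at least 2-fold. There the scatter of the 2 arrays of a line about the common transfection effect is the error, and nothing says that they came from separate cultures.

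The 24 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Of 574 listed genes, 359 were named on the array and 299 were tested. The median of a list within a line was placed among 10000 random lists of the same size matched on mean expression. Random lists leave out the correlation between members, so the percentile is a description.

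Genes were named by a rule. Among genes with the same sign in all 3 lines, the 12 higher and 12 lower genes with the largest smallest change were named, with genes called by limma, the 5 highest and 5 lowest changes of each line, and up to 4 members of a list with the largest mean change. Near-identical GAGE genes, small RNA genes other than the miR-135 hairpins, antisense and unnamed loci were counted and not named by this rule, which passed over 5 higher loci and 1 lower locus among those with the same sign in all lines. Other genes named were chosen after their values were seen. The tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were the fit without the block, no filter or a mean of at least 6, equal medians, quantile and cyclic loess normalization, an intensity trend, no variance moderation, the mean over probe sets of a gene, and each line left out in turn. Alternatives chosen after seeing the data were all probe sets, the correlations without MIR135A1, the same-sign count without GAGE genes and also without MIR135A1, and the immediate early list without EGR1 and FOSB. The planned comparison of genes with and without a seed site was not run, because no transcript sequences were used here.

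The procedure was tested on simulated data for 8620 genes with the variances drawn from the fitted prior and 200 genes altered in all 3 lines. For the miR-135a-3p comparison, 31.5% of 2-fold, 98% of 4-fold and 100% of 16-fold alterations were recovered, with 4, 8 and 13 false calls. A list shifted by −0.5 on the log2 scale was recovered in 20 of 20 runs, with 2 false calls of other lists. Errors were drawn independently for each gene, so these runs cannot show how lists of correlated genes behave. Of 200 genes altered 4-fold between ES-2 and OVCAR-3, 193 were recovered, with 4 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.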

Results

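Transcript levels were measured on 6 arrays, 3 from cells transfected with miR-blank and 3 from cells transfected with miR-135a-3p, in the ovarian cancer lines ES-2, OVCAR-3 and SKOV-3. The design asks which transcripts differ after transfection with the microRNA. Each line gave 1 array per transfection, so the lines are the replicates (n = 3). Values are normalised log2 signals, and a difference is always miR-135a-3p minus miR-blank.

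The signal of MIR135A1, the hairpin gene of miR-135a, rose in all 3 lines. It was 1.75 in ES-2, 2.26 in OVCAR-3 and 2.07 in SKOV-3 after miR-blank, and 12.57, 12.20 and 11.58 after miR-135a-3p. The mean log2 difference was 10.09 ± 0.67 (SD, n = 3), a mean fold of 1091 with a limma adjusted p of 4.83e-05. MIR135A2, a related hairpin gene, read 1.81, 1.75 and 1.62 after miR-blank and 1.88, 2.34 and 1.81 after miR-135a-3p. MIR135B read between 2.85 and 3.56 on all 6 arrays. The miR-blank signals of MIR135A1 lay at the 6.59, 13.95 and 12.34 percentile of all probe sets, so the fold depends on the floor of the array.

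**Figure D1:**
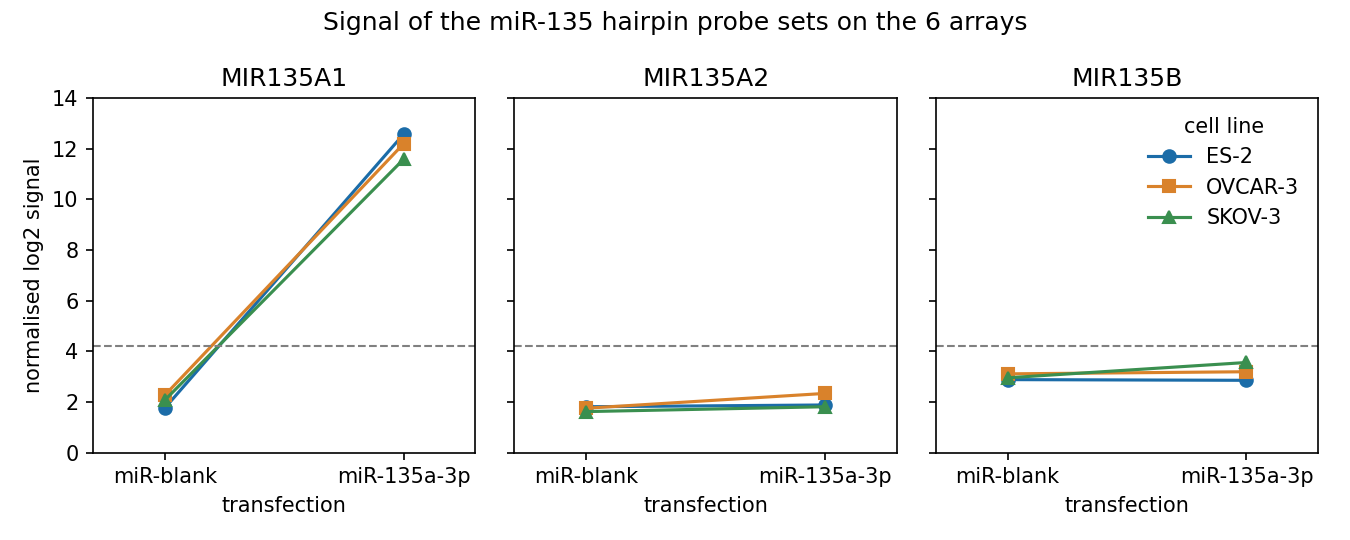
Normalised log2 signal (vertical axis) of the MIR135A1, MIR135A2 and MIR135B probe sets after each transfection (horizontal axis). Points are single arrays, lines join the arrays of a cell line, and the dashed line is the mean array median. MIR135A1 read 1.75 to 2.26 after miR-blank and 11.58 to 12.57 after miR-135a-3p.

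Genes with higher signal in all 3 lines included ENC1, an actin-associated kelch protein, with a mean log2 difference of 0.86 ± 0.26 (SD, n = 3), and TEX19, a germ cell factor, with 0.76 ± 0.13 (SD, n = 3). HENMT1, which methylates piRNAs, had 0.63 ± 0.04 (SD, n = 3) but read 2.26 and 2.86 in ES-2, not shown to be above background, and the protocadherin PCDHB15 had 0.71 ± 0.13 (SD, n = 3). The transcription factor EGR1 had the lower signal in all 3 lines, with −1.16 ± 0.71 (SD, n = 3), as did the chaperone clusterin, CLU, with −0.68 ± 0.16 (SD, n = 3). All these genes had a limma adjusted p of 0.999.

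The other genes of the higher group were the atypical cadherin FAT4 (0.83 ± 0.54, SD, n = 3), the peptide ligand APLN (0.43), the ubiquitin ligase MID2 (0.58) and the receptor CALCRL (0.59). PRDM6 (0.47), the kinase NEK11 (0.54), the esterase BCHE (1.14 ± 0.77, SD, n = 3) and the thioredoxin-binding protein TXNIP (0.97 ± 0.77, SD, n = 3) completed it. BCHE had 0.35 in ES-2, 1.89 in OVCAR-3 and 1.19 in SKOV-3. Mean log2 differences in the lower group were −0.58 for TMEM80, −0.52 for the splicing factor HNRNPA1, −0.58 for RNF213 and −0.83 ± 0.59 (SD, n = 3) for the antiviral membrane protein IFITM3. They were −0.51 for ZNF416, −0.82 ± 0.51 (SD, n = 3) for the YAP partner TEAD2, −0.44 for the centrosomal protein CSPP1, −1.01 for MYADM, and −0.56 for TMEM145. The proteoglycan VCAN had −1.88 in ES-2, −0.37 in OVCAR-3 and −0.76 in SKOV-3. HNRNPA1, with an SD of 0.03 over the lines, has many pseudogenes, and IFITM3 and PCDHB15 have close paralogs, so the values of these genes are uncertain. HENMT1 in ES-2, CALCRL in ES-2 and SKOV-3 and VCAN in OVCAR-3 lay below the array median on both arrays, so those differences were not shown to be above background. On 1 array of the line, ENC1 in OVCAR-3 and SKOV-3 and PCDHB15 in ES-2 and OVCAR-3 lay below the array median. In OVCAR-3, BCHE (2.67 after miR-blank), PRDM6 and CLU did as well, so the sizes of these differences are uncertain. Leaving out 1 line moved 6 of the 24 means by over 1.5 times. Without SKOV-3, EGR1 had −0.76, FAT4 0.52, TXNIP 0.55 and TEAD2 −0.53, and without ES-2, IFITM3 had −0.49 and VCAN −0.57.

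limma called 1 of 8620 genes, MIR135A1. At an unadjusted p under 0.05 there were 251 genes, 100 higher and 151 lower, where chance gives 431. The same sign in all 3 lines was held by 1979 genes, 23.0%, where chance gives 25%. At least 1.5-fold in the same direction in all 3 lines was reached by 8 genes, 7 higher and 1 lower, and with the sign of the ES-2, OVCAR-3 or SKOV-3 pair turned by 3, 2 and 4 genes. Without MIR135A1 and the GAGE genes, which are near-identical, the count was 5, 4 higher and 1 lower, against the same 3, 2 and 4. A mean of at least 2-fold was reached by 21 genes, and 14 of them had the same sign in all lines. Without SKOV-3, limma called 4 genes. Besides MIR135A1 these were the receptor EDA2R (−1.99, adjusted p 0.0102), EMP2 (−1.53, adjusted p 0.0102) and MID1 (−1.25, adjusted p 0.0411), with −0.13, −0.02 and 0.59 in the line left out. EDA2R read 4.53 and 4.40 in SKOV-3, near the array medians, against 6.65 and 6.81 after miR-blank in ES-2 and OVCAR-3. There was thus less room for a fall of EDA2R in SKOV-3. Without variance moderation limma called 0, with 337 genes at an unadjusted p under 0.05.

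**Figure D2:**
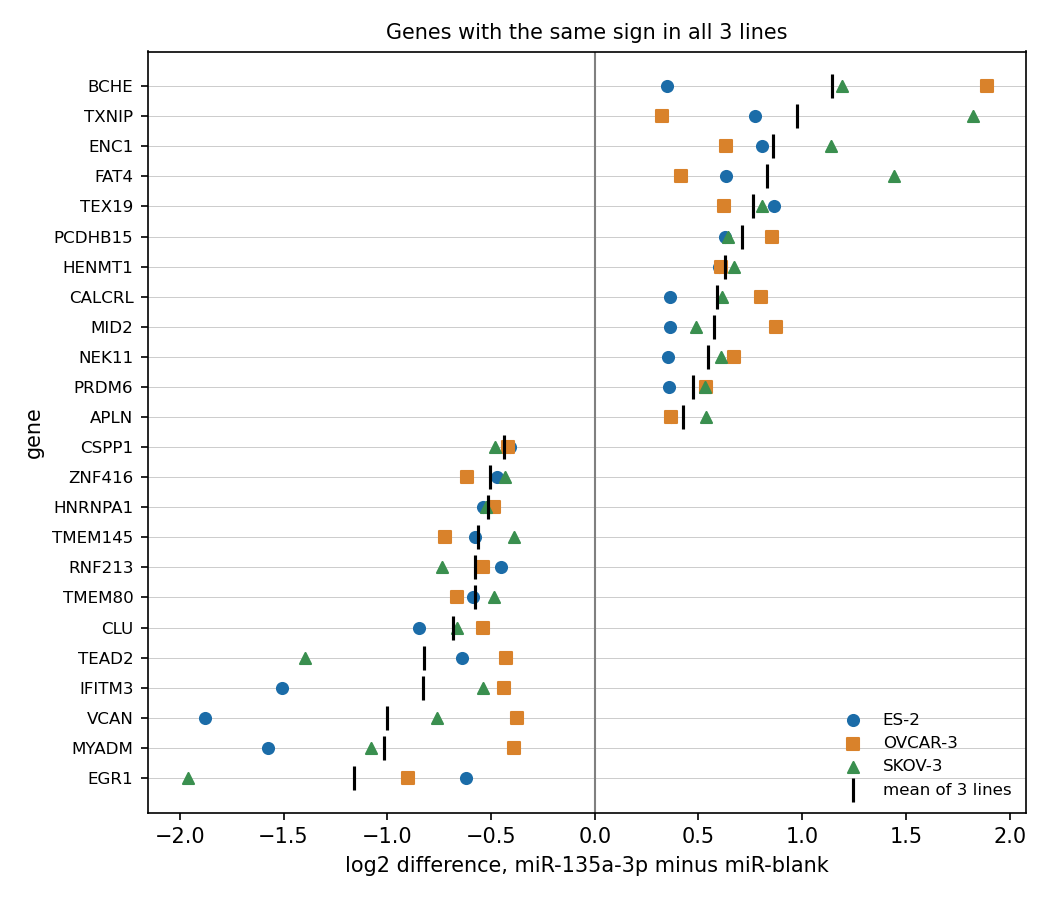
Log2 difference, miR-135a-3p minus miR-blank (horizontal axis), of the 24 named genes with the same sign in all 3 lines (vertical axis). Symbols are the single difference of each cell line and black bars the mean of 3 lines. EGR1 had −0.62 in ES-2, −0.90 in OVCAR-3 and −1.96 in SKOV-3.

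Among the gene lists, the immediate early and MAPK target genes had the lowest median of the mean differences (−0.29) and the lowest camera p, while the NF-kB list had the lower mean (−0.32 against −0.22). Of 19 tested members, 8 had lower signal in all 3 lines and 0 had higher signal in all 3. EGR1 was followed by FOSB (−0.92 ± 1.36, SD, n = 3), FOS (−0.85 ± 0.92, SD, n = 3) and DUSP6 (0.74 ± 1.12, SD, n = 3). The list median was −0.31 in ES-2, −0.15 in OVCAR-3 and −0.33 in SKOV-3, at percentiles 0, 7.96 and 0.02 of random lists. Random lists leave out the correlation between members, so these percentiles describe the list and do not test it. In SKOV-3 the members parted. FOS (−1.91), FOSB (−2.49), DUSP1 (−1.96) and JUNB (−1.65) were lower, while DUSP6 (1.81), FOSL1 (1.68), ETV4 (1.57) and DUSP4 (1.27) were higher. The list had a camera p of 0.00249 and an adjusted p of 0.0598, and an adjusted p of 0.680 with an estimated correlation. camera called it without OVCAR-3 (adjusted p 0.0407), without SKOV-3 (adjusted p 0.00849) and without a filter (adjusted p 0.026), but not without ES-2 (adjusted p 0.137). It was also not called without the block (adjusted p 0.182), at a mean of at least 6 (0.15) or with the mean over probe sets (0.0926). The same held after quantile normalization (0.0597) and for the list less EGR1 and FOSB (0.136).

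**Figure D3:**
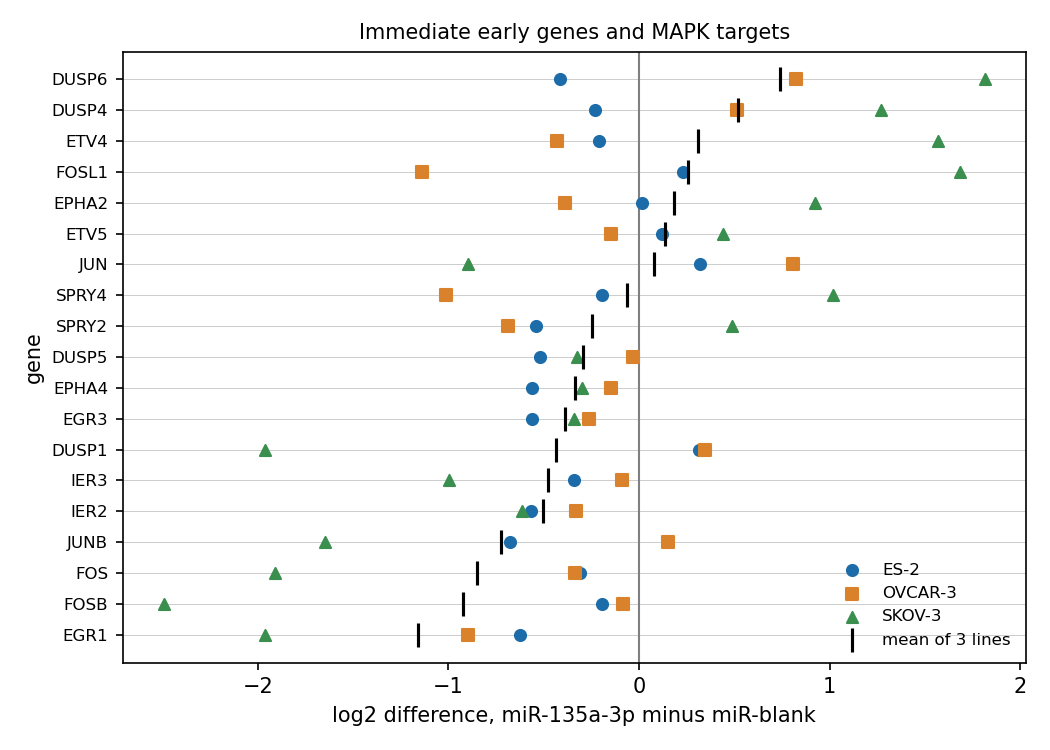
Log2 difference, miR-135a-3p minus miR-blank (horizontal axis), of the 19 tested immediate early and MAPK target genes (vertical axis). Symbols are the single difference of each cell line and black bars the mean of 3 lines. The list median was −0.31, −0.15 and −0.33 in ES-2, OVCAR-3 and SKOV-3.

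The inflammatory NF-kB list had a median of −0.27 over its 12 tested genes, with 3 lower and 3 higher in all lines, and medians of −0.09 in ES-2, 0.10 in OVCAR-3 and −0.41 in SKOV-3. Its members included the cytokine LIF, at −0.27 in ES-2, 1.17 in OVCAR-3 and 0.69 in SKOV-3. The chemokines CCL20 (−2.92), CXCL8 (−2.74) and CXCL2 (−2.21) were low in SKOV-3 and CXCL3 in OVCAR-3 (−1.38) and SKOV-3 (−1.12). The mesenchymal list had a median of 0.40 over 8 genes, with 0.13 in ES-2, −0.00078 in OVCAR-3 and 0.51 in SKOV-3. FN1 differed by 2.22 in OVCAR-3, SNAI2 by 2.10 and TWIST2 by 1.61 in SKOV-3, and SNAI1 by −1.23 in ES-2. VIM, the intermediate filament vimentin, had 0.12, 0.46 and 0.53 in ES-2, OVCAR-3 and SKOV-3. In the ovarian cancer list, with a median of 0.17 over 10 genes, MSLN had 1.41 in SKOV-3, WT1 had a mean of 0.46, and the secreted phosphoprotein SPP1 had −1.73 in ES-2 and 2.48 in SKOV-3. The hypoxia and glycolysis list had a median of 0.04 over 14 genes, led by NDRG1 (0.57 ± 0.30, SD, n = 3). The TGF-beta list had −0.12 over 8 genes, led by JUNB (−0.72), and the pro-apoptotic list −0.20 over 8. The pro-apoptotic medians were 0.05, −0.09 and −0.45 in ES-2, OVCAR-3 and SKOV-3. There BAX, with −0.26, −0.33 and −0.37, was the 1 member lower in all lines, and BBC3 had 0.10, 0.38 and −1.02. Of 3 tested leukocyte markers, CD68 had 2.24 and TYROBP 0.70 in SKOV-3, and the list medians were −0.05, 0.06 and 0.70 in ES-2, OVCAR-3 and SKOV-3.

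These 7 lists had camera adjusted p from 0.136 to 0.138 at the preset correlation. With an estimated correlation their camera adjusted p ran from 0.680 to 0.9625, and their unadjusted p from 0.126 to 0.401. camera called 0 of 24 lists, with 8 at an unadjusted p under 0.05 at the preset correlation and 0 with an estimated correlation, and fry gave 2 at an unadjusted p under 0.05, hypoxia (0.00648) and ovarian cancer (0.0393). The G1/S list had a median of 0.07 and an adjusted p of 0.186. The G2/M list had medians of 0.07, 0.10 and −0.23 in ES-2, OVCAR-3 and SKOV-3, at percentiles 97.68, 100 and 0 of random lists, and an adjusted p of 0.729. The lists of ER chaperones (0.158), Wnt targets (0.389), cholesterol synthesis (0.394), epithelial genes (0.705), microRNA machinery (0.733), ribosomal proteins (0.864), p53 targets (0.864) and interferon response (0.864) had the adjusted p given. Those of anti-apoptotic genes, amino acid response, heat shock, oxidative phosphorylation, YAP and TAZ targets and endothelial markers had 0.958. The median, mean and test differed in sign for the interferon and heat shock lists. In every list 0 members passed limma over all genes tested and 0 passed when adjusted over the list alone.

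Within single lines, the 5 highest and 5 lowest protein-coding genes outside the GAGE family are given. In ES-2, the protocadherins PCDHB13 (1.85) and PCDHB14 (1.75), ZNF429 (1.24), NAP1L3 (1.23) and PRICKLE1 (1.15) stood highest, and ATF7IP2 (−2.95), the desmosomal cadherin DSG2 (−2.63), EDA2R (−2.31), TMEM168 (−2.12) and SERINC2 (−2.09) lowest. In OVCAR-3, fibronectin, FN1 (2.22), CAMK2D (1.99), BCHE (1.89), TM4SF1 (1.53) and ARHGDIB (1.34) stood highest. The metalloproteinase inhibitor TIMP1 (−2.28), RHOBTB3 (−2.13), RALGPS2 (−1.78), CD47 (−1.67) and EDA2R (−1.66) stood lowest there. In SKOV-3, the neurotensin receptor NTSR1 (3.03), ACTL8 (3.01), the bombesin receptor GRPR (2.99), fibrillin FBN1 (2.89) and SAGE1 (2.58) stood highest. IFITM2 (−6.28), KRCC1 (−3.41), thrombospondin THBS1 (−3.39), IGFBP3 (−3.36) and CCL20 (−2.92) stood lowest there. IFITM2 read 10.39 after miR-blank and 4.12 after miR-135a-3p in SKOV-3.

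Differences of at least 2-fold numbered 58 in ES-2 (14 higher, 44 lower), 58 in OVCAR-3 (25 higher, 33 lower) and 345 in SKOV-3 (202 higher, 143 lower). In OVCAR-3 the balance turned at equal array medians (29 higher, 27 lower) and without a filter (68 higher, 61 lower). The SD of the difference over genes was 0.30, 0.30 and 0.48. At least 2-fold, in either direction, was reached in 1 line by 393 genes, in 2 lines by 31 and in 3 lines by 2. Of genes past 2-fold in both ES-2 and OVCAR-3, 1 was higher in both, 3 were lower in both and 2 moved in opposite directions. The same counts were 1, 6 and 6 for ES-2 and SKOV-3, and 8, 1 and 9 for OVCAR-3 and SKOV-3. MIR135A1 was among the genes higher in both lines of every pair. With 1 array per transfection, these differences have no replicate check. The log2 differences correlated across genes at a Pearson r of 0.220 between ES-2 and OVCAR-3, 0.0455 between ES-2 and SKOV-3 and −0.0330 between OVCAR-3 and SKOV-3. Spearman's rho was 0.116, −0.0798 and −0.142. Genes are not independent replicates, and without MIR135A1 the Pearson values were 0.0915, −0.0414 and −0.121.

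**Figure D4:**
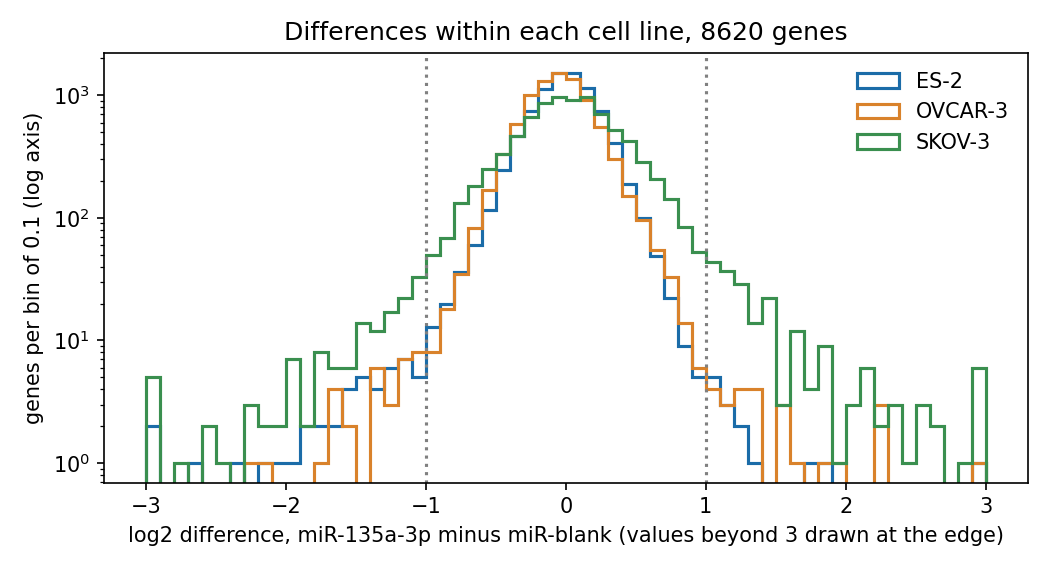
Genes per bin (vertical log axis) by log2 difference, miR-135a-3p minus miR-blank (horizontal axis), for each cell line. Dotted lines mark 2-fold, and 345 genes lay beyond them in SKOV-3 against 58 in ES-2 and 58 in OVCAR-3.

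The lines themselves differed in mesenchymal and epithelial genes. Vimentin, VIM, had a mean signal of 10.79 in ES-2, 5.31 in OVCAR-3 and 9.86 in SKOV-3 (ES-2 minus OVCAR-3 5.48, limma adjusted p 1.9e-05). FN1 was highest in ES-2 at 11.27, against 5.52 and 4.90, and SNAI2, a repressor of epithelial genes, read 10.77, 4.82 and 9.52. The tight junction gene CLDN7 was highest in OVCAR-3 at 9.11, against 5.06 in ES-2 and 5.01 in SKOV-3. OCLN read 5.47 in ES-2, 8.94 in OVCAR-3 and 8.47 in SKOV-3, and MARVELD2 3.78, 4.70 and 7.09. KRT7 read 6.56, 4.34 and 5.63 in ES-2, OVCAR-3 and SKOV-3. PAX8, a transcription factor of the Mullerian lineage, was highest in SKOV-3 at 8.46, against 4.49 and 4.22. SPP1 read 6.75, 12.72 and 10.44, and CCNE1 7.11, 8.23 and 7.58.

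Of 8 tested mesenchymal genes, 4 were higher and 0 lower in ES-2 than in OVCAR-3, 4 were lower and 0 higher in OVCAR-3 than in SKOV-3, and 1 was higher and 2 lower in ES-2 than in SKOV-3. Of 8 epithelial genes, 3 were lower and 1 higher in ES-2 than in OVCAR-3, 2 were lower and 0 higher in ES-2 than in SKOV-3, and 2 were higher and 1 lower in OVCAR-3 than in SKOV-3. Of 10 ovarian cancer genes, 2 were lower and 0 higher in ES-2 than in either other line, and 1 was lower and 0 higher in OVCAR-3 than in SKOV-3. limma called 1420 genes between ES-2 and OVCAR-3, 746 of them higher in ES-2. It called 1046 between ES-2 and SKOV-3, 418 higher in ES-2, and 1255 between OVCAR-3 and SKOV-3, 483 higher in OVCAR-3. Each line entered with 2 arrays that also differed in transfection.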

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

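The threshold of 2-fold in opposite directions, used here to pick genes, was chosen after the results were seen. Among the named genes and the tested members of the gene lists, 8 genes differed by at least 2-fold in opposite directions in a pair of lines, and none of these differences between lines was tested, since each line has 1 array per transfection. ZNF429 had a log2 difference of 1.24 in ES-2 and −1.35 in SKOV-3. NAP1L3 had 1.23 in ES-2 and −2.1 in SKOV-3. TIMP1 had 1.28 in SKOV-3 and −2.28 in OVCAR-3, and SAGE1 2.58 in SKOV-3 and −1.01 in ES-2. SAGE1 read 3.32 and 2.31 in ES-2, below the array median on both arrays, so that difference was not shown to be above background. ZNF429 (3.85) and NAP1L3 (4.08) lay below the array median after miR-blank in ES-2. NAP1L3 also did after miR-135a-3p in SKOV-3 (3.88), so the sizes of these differences are uncertain. KRT7 had 1.03 in OVCAR-3 and −1.53 in SKOV-3, and SPP1 2.48 in SKOV-3 and −1.73 in ES-2. KRT7 in OVCAR-3, with a line mean of 4.34, lay below the array median after miR-blank, so the size of that difference is uncertain. FOSL1 had 1.68 in SKOV-3 and −1.14 in OVCAR-3, and SPRY4 1.02 in SKOV-3 and −1.01 in OVCAR-3. Among unnamed probe sets, 12 were at least 1.5-fold higher (2) or lower (10) in all 3 lines. With the sign of the ES-2, OVCAR-3 or SKOV-3 pair turned, this count was 10, 10 and 31. limma over all probe sets called MIR135A1 and no unnamed probe set.

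Log2 differences spread wider in SKOV-3 than in the other lines. Against noise at low signal as the whole cause, the ratio of the SKOV-3 spread to the mean of the other lines was 1 among 14802 dim probe sets and 1.81 among 3805 bright genes. A further normalization left the ratio nearly unchanged, at 1.58 as deposited and 1.57 after cyclic loess. RMA already makes the distributions equal, and the probe signals were not processed again. These ratios therefore cannot test the normalization of the deposited values. Against RNA of another line in a SKOV-3 array, the 50 genes highest in OVCAR-3 over SKOV-3 had a median SKOV-3 difference of 0.112 and those highest in ES-2 −0.0588, where the lines differed by 3.87 and 4.29. A difference in culture, RNA quality or amplification between the SKOV-3 arrays, which could act on bright genes, stays open. A stronger response of SKOV-3 to the microRNA and an effect of the deposited normalization stay open as well. All are untested with 1 pair of arrays.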

How the results depend on the processing

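The settings with all probe sets, without MIR135A1, without GAGE genes, with or without MIR135A1, and without EGR1 and FOSB were chosen after the results were seen. limma called 1 gene, MIR135A1, without the replicate block (adjusted p 4.68e-04) and with all probe sets, 0 without variance moderation (337 at an unadjusted p under 0.05) and 1 to 4 with a line left out, the 4 without SKOV-3. The adjusted p of MIR135A1 ranged from 1.64e-08 to 0.00302 over the other settings and was 0.994 without moderation. The count at least 1.5-fold alike in all lines, 8, was 4 at a mean of at least 6, 5 after quantile normalization, and 24 to 50 with a line left out, where 2 lines must match (27 higher and 15 lower without ES-2, 18 and 32 without OVCAR-3, 12 and 12 without SKOV-3). It was 6 without GAGE genes and 5 without MIR135A1 as well. Without a filter, where 14884 genes entered, at least 2-fold was reached by 134 genes in ES-2 and 129 in OVCAR-3, and at a mean of at least 6, with 6049 genes, by 32 and 34. Without MIR135A1 the correlations were 0.0915, −0.0414 and −0.121. Without a filter they were 0.123, 0.0234 and −0.0531, and at a mean of at least 6 they were 0.278, 0.0816 and −0.0096. A bootstrap over genes gave an SD of 0.109, 0.0817 and 0.0832. Genes are not replicates, so this SD does not measure how stable the correlations are. camera called 2 lists without a filter (NF-kB and immediate early, lower) and 1 to 3 with a line left out (mesenchymal without ES-2, G1/S, NF-kB and immediate early without OVCAR-3, G2/M and immediate early without SKOV-3). With an estimated correlation it called 0 lists (lowest adjusted p 0.680). It called 0 without the block and 0 with the immediate early list less EGR1 and FOSB (adjusted p 0.136). The cause of these moves was not tested beyond the numbers of genes and lines. The ES-2 and SKOV-3 correlation changed sign without MIR135A1. The balance of higher and lower genes turned for the same-sign count without OVCAR-3, and in OVCAR-3 at equal medians (29 and 27) and without a filter (68 and 61). No mean or line value of a gene named by the same-sign or line rule changed sign in the settings run. Counts between lines stayed within 1.5 times. Of the alternative values of single genes, 446 kept their sign and call or, in a line, lay within 1 SD over genes of the value given. Settings that alter only the test or the filter return the same mean or line value. Genes chosen for the same sign in all lines also keep it with a line left out. Much of this count and of the kept signs was therefore fixed in advance and does not measure stability. Leaving out a line still moved 6 of 24 means by over 1.5 times. MIR135A1 lost its call (above), and 2 line values moved further than that SD, RHOBTB3 (−1.73) and CD47 (−1.26) in OVCAR-3 after quantile normalization. The seed site comparison was not run. With no detection calls, signal over background limits the dim genes.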

Other observations

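The tests of related precursors, of swapped labels, of a signal shared by GAGE probe sets, of protocadherin members outside the named genes and of a signal shared by protocadherin probe sets were chosen after the results were seen. The genes named here were also chosen after their values were seen. Clustered gene families showed their own patterns. Of 16 protocadherin beta genes, 9 had higher signal in all 3 lines and 0 lower, with medians of 0.47 in ES-2, 0.25 in OVCAR-3 and 0.44 in SKOV-3. The medians kept their sign under the equal-median, quantile and cyclic loess scalings, a check chosen after the results were seen, but the count of 9 was 5 after quantile and 7 after cyclic loess normalization. PCDHB4 had a log2 difference of 2.16 and PCDHB3 of 1.67 in SKOV-3. Of 7 GAGE genes, which encode cancer-testis antigens, 6 had higher signal in all lines, and the medians of these 6 were 0.27, 1.45 and 1.29 in ES-2, OVCAR-3 and SKOV-3. These 6 were the GAGE genes that passed the filter, and their differences had a mean correlation of 0.997, so these near-identical genes may be a single signal. GAGE10, below the filter, parted from them. It had the largest difference of the family in ES-2, where it read 3.79 and 4.79, with −0.17 in OVCAR-3 and 0.12 in SKOV-3. The 6 MIR3689 hairpins had medians of −0.19, −0.78 and 2.64. All 6 read lowest on the SKOV-3 miR-blank array, so it was this control array that stood apart. MIR3689A read 6.92 there, 9.53 after miR-135a-3p in SKOV-3 and 8.80 to 9.57 on the ES-2 and OVCAR-3 arrays. Whether the hairpins share a single signal was not tested. Of these hairpins, MIR3689D1 had a difference of 0.67 in SKOV-3, apart from the others.

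MIR135A1 signal rose in all 3 lines. Against activity of the wider chromosomal region, the 10 nearest named protein-coding genes had a median mean difference of −0.0884, the highest being DUSP7 at 0.309. These neighbours cannot show whether the hairpin gene alone was activated. Against probes that read related precursors, the larger mean difference of MIR135A2 and MIR135B was 0.282. That 3 of 3 lines had the higher signal on the array labelled miR-135a-3p restates the pattern and does not test swapped labels. A candidate explanation that stays open is that the probe set read the transfected material itself.

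Of 16 protocadherin beta genes, 9 had higher signal after miR-135a-3p in all 3 lines, while PCDHB2 (−0.14) and PCDHB6 (−0.20) had lower means and 0 of the 10 tested passed limma. The median of all 16 members, 0.459, lay at percentile 100 of random lists, and that of the 13 members other than PCDHB13, PCDHB14 and PCDHB15, 0.325, also at percentile 100. The members differed by 2.03 or more in each line, but in ES-2 and OVCAR-3 only 1 member had a line mean of at least 5, and in SKOV-3 the 10 members with a line mean of at least 7 ranged from 0.03 to 1.03, so a signal shared by similar probe sets stays open. Paralogs of a cluster are not independent, which random lists leave out, and 6 members lay below the filter of the test. A joint rise of the cluster remains a hypothesis found and tested on the same data.

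A rise of germline genes as a group was a hypothesis after TEX19, HENMT1 and the GAGE genes were seen. Of 99 germline genes listed, 51 were named on the array and 17 passed the filter. The 8 tested listed genes not counted as seen had a median of 0.0151, at percentile 60.13 of random lists. These 8 showed no joint rise, but the filter left out dim germline genes, so they cannot decide for the group. ACTL8, already seen in SKOV-3, was among them, and without it 7 genes lay at percentile 44.01. Outside GAGE, 2 listed genes were at least 0.5 higher in all lines, of which HENMT1 was dim in ES-2, so a signal shared by GAGE probe sets stays open.

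The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 3 of the 10 splits, the real one included, limma called at least as many genes as the 1 of the real split. The highest other count, 227, came from splits that part the SKOV-3 pair alone. With the line as a block, these splits are the same fit with the sign turned, so 1 fit was counted repeatedly. That fit sets the SKOV-3 difference against the scatter of the other pairs, so it restates the wider spread of SKOV-3. The 3 other splits that part all pairs called 0. For gene lists, 10 of 10 splits, the real one included, called at least the 0 of the real split, which any split reaches. The highest other count was 4, also from the splits that part the SKOV-3 pair alone.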
